A study of Mus musculus with 6 samples.

How the data were processed

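Bone marrow was taken from C57BL/6 mice of 12 weeks with 2, 1 or no intact copies of Diap1, the gene named in older annotation for the formin mDia1 (current symbol Diaph1). These genotypes are called WT, Het and KO here. Per the labels' protocols, marrow of 4 mice of a genotype was pooled, cells positive for both Gr1 and Mac1 (surface markers of granulocytes and monocytes) were taken with magnetic beads, and the remaining cells were depleted down to uncommitted progenitors. Total RNA was made from both fractions and sequenced by Illumina protocols. The 6 libraries are called by genotype and fraction (Lin- and Gr1+Mac1+), with 1 library in each of the 6 groups.

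The deposited values are FPKM, fragment numbers scaled to transcript length and to the mapped total of the library, for 23746 gene loci on mm10. Per the file headers, each locus has an FPKM, a lower and an upper bound and a status. Per the submitters' processing notes, TopHat2 2.0.7 and Cufflinks 2.0.2 were used and the build was mm10; their roles and the annotation are not given in the sources used here. FPKM divides by the library's total, so a few very abundant genes lower the values of all others. The 10 most abundant genes held 8.72% to 10.5% of the summed FPKM in the Lin- libraries and 25.1% to 27.8% in the Gr1+Mac1+ libraries. Genes with near-identical copies are uncertain, since fragments can be split between the copies. This concerns the globin, histone, H2-Q, Ear, Lgals and ribosomal protein genes. Small RNA genes and genes that overlap others, such as Snhg9 and Scarna10, are uncertain as well. Locus starts were read as 0-based, since 12238 starts matched an annotated transcript start of the GENCODE mouse annotation after adding 1 and 1154 matched without; coordinates below are 1-based.

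The files hold no fragment counts. The width of the deposited 95% intervals follows the square root of a fragment number, and among genes with fewer than 50 implied fragments 60.9% to 63.3% gave a whole number within 0.05. On that basis the libraries held an implied 10390000 (WT), 10010000 (Het) and 9420000 (KO) fragments in the Lin- fraction and 11600000 (WT), 10240000 (Het) and 8630000 (KO) in the Gr1+Mac1+ fraction, rounded to 10000. The intervals cover counting error only and say nothing of the spread between mice. Standard errors of log2 ratios between 2 libraries below come from these intervals and carry the same limit.

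Before the data were examined, the comparisons, the size rule, the main alternatives, 30 gene lists and the rule for naming genes were fixed; most tests of explanations and some alternatives were chosen later and are marked where they are given. With 1 library per group, no test between genotypes within a fraction was possible. The 2 fractions of a pool come from the same mice and are not replicates of the genotype. They were therefore not joined for a test, and no p-value between genotypes is given. A gene counts as higher or lower between 2 libraries by a rule of size: at least 2-fold on the log2(FPKM + 1) scale, FPKM of at least 5 in the higher library, deposited intervals that do not overlap, and status OK in both. A gene list is described by the median log2 ratio of its measured members (mean FPKM of at least 1 in the fraction, at least 5 members) and the percentile of that median among 10000 random lists of the same size matched on mean expression in 20 bins. It stands apart under 2.5 or over 97.5, as a description of these libraries. Of 816 list symbols, 808 matched, 8 of them by an older symbol. The values of 1 list are not reported here.

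The 2 fractions were compared with limma 3.58.1 (R 4.3.3) on log2(FPKM + 1), with trend, the pool as a block, 11489 genes with mean FPKM of at least 1, and Benjamini-Hochberg adjusted p under 0.05. Both fractions of a pool come from the same mice, per the labels' protocols, which is where the pairing comes from. The deviations of the 2 fractions of a pool from their fraction means correlated across genes by 0.10 (WT), -0.06 (Het) and -0.01 (KO). The 3 pools differ in genotype, so the 2 residual degrees of freedom hold the interaction of genotype and fraction as well as noise. Other steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.

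The named genes are Diap1 and Cd14 in all libraries; the 10 genes higher and 10 lower with the largest log2 ratio among those past the size rule in each KO comparison, and 5 and 5 in each Het comparison; up to 4 passing members of each list that stands apart or has at least 2 of them; up to 3 of the most abundant members of the first 5 lists; and between fractions the 10 with the largest log2 ratio in each direction, past the threshold and in 1 direction in all 3 pools, with up to 4 per list. Unnamed, duplicated, Gm, Rik, Mir, Snor and rRNA symbols were passed over. Alternatives were other pseudocounts (0.1 and 5), other level filters, rescaling by the median ratio, 3-fold in place of 2-fold, no interval criterion, and for the fractions no pool block, no trend and each pool left out. Correlations of log2 ratios were computed on values limited to 1 in size, a choice made after seeing that a few extreme genes dominated them.

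The size rule and list percentiles were tested on simulated data for the KO and WT Lin- libraries, with 200 of 15554 genes changed. The rule recovered 95% of 2.5-fold and 96% of 4-fold changes and called 2 unchanged genes, and 1 of 100 unchanged lists stood apart. All libraries of that simulation were drawn from the WT Lin- levels with counting error only. Its changed genes and unchanged lists were taken from the more abundant genes. These rates therefore hold no spread between mice or pools and are not false-call rates of the real comparisons. The limma step was tested on simulated data for the fraction comparison, with 200 of 11489 genes changed; it recovered 77% of changes of 1 and 91% of changes of 2 on the log2 scale, and 1.75% of its calls were false. Its noise was independent between libraries, with the genes' spreads shuffled, and its changed genes were taken from the more abundant ones. Far more genes were called between the real fractions, so 1.75% is not the false-call rate of that comparison.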

Results

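Gene expression was measured in 2 fractions of mouse bone marrow, Lin- progenitors and Gr1+Mac1+ myeloid cells, from WT, Het and KO pools of 4 mice each. The comparisons ask what loss of 1 or both copies of Diap1, a formin that nucleates actin filaments, does to expression in progenitors and in myeloid cells. Each value of a genotype and fraction is from 1 library, without replicates. Between 10795 and 11315 genes had an FPKM of at least 1 in a library.

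Diap1 (chromosome 18, 37844825 to 37935411, mm10) was lower in both fractions with each copy lost. In Lin- cells its FPKM was 36.0 in WT (deposited 95% interval 34.4 to 37.6), 24.2 in Het (22.9 to 25.6) and 6.07 in KO (5.38 to 6.75). In Gr1+Mac1+ cells it was 57.1 in WT (55.2 to 59.0), 34.1 in Het (32.5 to 35.6) and 4.07 in KO (3.49 to 4.66). The KO level was thus 16.9% of WT in Lin- and 7.13% in Gr1+Mac1+ cells, and the Het level 67.4% and 59.7%. The deleted part of the gene is not stated in the labels, so the remaining KO signal cannot be placed within or outside it.

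Cd14, the co-receptor for bacterial lipopolysaccharide on myeloid cells, lies 1.12 Mb from Diap1 on the same chromosome (36725067 to 36726654). Its FPKM in Gr1+Mac1+ cells was 16.9 in WT (15.1 to 18.8), 71.4 in Het (67.4 to 75.4) and 132 in KO (126 to 138). In Lin- cells it was 0.284 in WT, 1.95 in Het and 2.37 in KO, below the level of 5 that the size rule asks for.

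**Figure D1:**
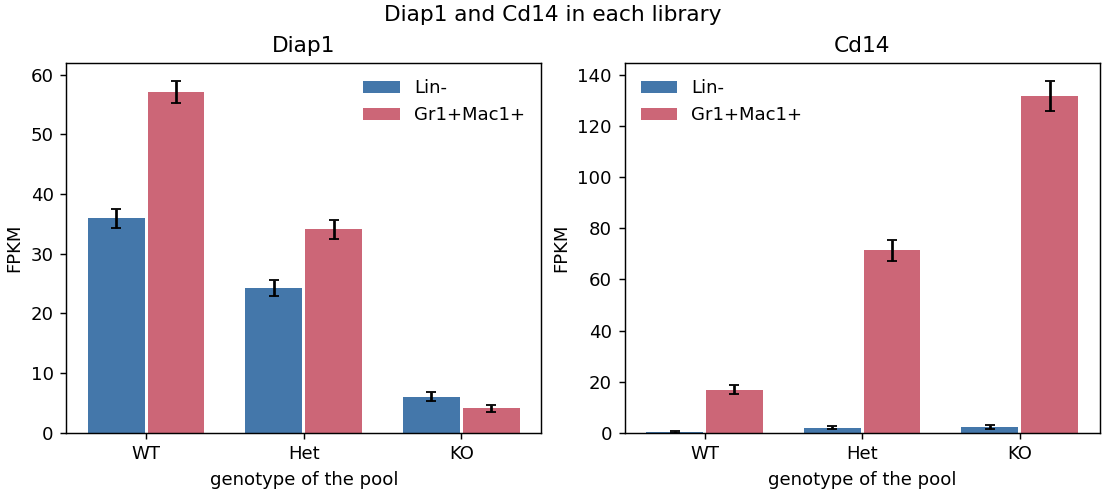
FPKM of Diap1 (left) and Cd14 (right) in each of the 6 libraries, by genotype of the pool, with bars for the deposited values and error bars for the deposited 95% intervals, which cover counting error only. Cd14 in Gr1+Mac1+ cells was 16.9 in WT, 71.4 in Het and 132 in KO.

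In KO against WT Gr1+Mac1+ cells, Cd14 was among only 5 genes higher by the size rule, with a log2 ratio of 2.89 (counting SE 0.08), and 11 genes were lower. Cd5l, a protein secreted by macrophages, was higher by 1.26, from an FPKM of 4.81 to 12.9, and Dnajc12, a co-chaperone, by 1.08. Rps27 (FPKM 5.79 to 571) and Lgals6 (1.14 to 7.43) also passed, and both have near-identical copies. Apart from Diap1, at -3.52, the lower genes included several of red cell formation. Klf1, an erythroid transcription factor, had a log2 ratio of -1.08 (FPKM 17.2 to 7.61) and Rhag, a red cell membrane protein, one of -1.04 (27.2 to 12.7). Hbq1b, a globin gene with close copies, stood at -1.31, Ces2g at -1.04, Lax1 at -1.02, Cldn13 at -1.02 and Pla2g12a at -1.01. Snhg9 was listed at 0 in KO and at 28.6 in WT.

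Of the 31 measured erythroid genes, 29 had a negative log2 ratio in KO Gr1+Mac1+ cells, with a median of -0.81 and a percentile of 0 among random lists; 2 passed the size rule. No other list but the sex-linked genes, at 0.48, had a median above 0.26 in size in this comparison. Of the 31 measured genes of CD14 and Toll-like receptor signalling, Cd14 alone passed, and the list median was 0.02 (percentile 66.5). Its abundant member Myd88 was at 52.0 in WT and 52.9 in KO, and Lbp at 41.2 and 45.9. NF-kB feedback genes had a median of 0.03 and inflammatory cytokines one of 0.05, neither apart. Monocyte and macrophage genes stood apart at 0.12, with 1 of 28 passing. Lists higher by small medians were primary granule proteins at 0.20, secondary and tertiary granule proteins at 0.11, eosinophil, basophil and mast cell genes at 0.22, stromal and endothelial genes at 0.25, type I interferon genes at 0.11 and T and NK cell genes at 0.10. Dendritic cell and MHC class II genes at -0.10, mitosis genes at -0.05, DNA replication genes at -0.07, ribosomal proteins at -0.03, replication-dependent histones at -0.12 and immediate-early genes at -0.06 stood apart as lower. With mean FPKM of at least 5 monocyte genes (0.05) and T and NK cell genes (0.11) no longer stood apart, nor did the latter (0.04) with a pseudocount of 5 or histones (-0.07) without the filter on low values.

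Cytoskeletal lists moved little in KO Gr1+Mac1+ cells. Of 9 measured formins only Diap1 passed, and Fmnl1, the most abundant, was at 142 in WT and 138 in KO, with Fmnl3 at 16.1 and 18.2. SRF and MRTF cytoskeletal targets had a median of 0.04, not apart, with none passing. Actb was at an FPKM of 3248 in WT and 3482 in KO. The orthologues of human 5q genes, a list that holds Diap1 and Cd14, had a median of 0.06 with those 2 genes passing in opposite directions.

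In KO against WT Lin- cells, 15 genes were higher and 4 lower by the size rule. Podxl, a sialomucin of progenitors and endothelium, had a log2 ratio of -2.75 (FPKM 9.96 to 0.629), Diap1 one of -2.39 and Moap1, a BAX-binding protein, one of -1.77 (5.68 to 0.953). The higher genes included adult globins, Hbb-b2 at 1.44 (268 to 729), Beta-s at 1.19 (1041 to 2377) and Hbb-b1 at 1.04, which share fragments. Tmod1, which caps actin filaments in red cells, was at 1.06, Fn3k at 1.77, Tac2 at 1.13, Ypel4 at 1.13 and the histone genes Hist3h2ba and Hist2h2bb at 1.54 and 1.31. Rps27 (4.63 to 352) and H2-Q7 (6.77 to 27.1) had the largest ratios on the log2(FPKM + 1) scale and are uncertain for their near-identical copies.

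No list of KO Lin- cells other than the erythroid genes had more than 1 member past the size rule, but 15 lists stood apart as higher and 4 as lower, where 1.5 in all would be expected by chance for independent genes. Monocyte and macrophage genes had the largest median apart from the sex-linked genes, 0.40, with 16 of 17 positive. Secondary and tertiary granule proteins followed at 0.29, eosinophil, basophil and mast cell genes at 0.26, granulocyte and monocyte lineage regulators at 0.24, stromal and endothelial genes at 0.23, NADPH oxidase subunits at 0.20, stem and progenitor genes at 0.18 and mature neutrophil genes at 0.15. Smaller medians apart as higher were 0.13 for type I interferon genes, 0.12 for primary granule proteins, 0.08 for erythroid genes and 0.05 for both DNA replication genes and ribosomal proteins. T and NK cell genes had a median of -0.48, with 14 of 17 negative, megakaryocyte and platelet genes one of -0.25 with 16 of 20 negative, B lineage genes one of -0.14 with 7 of 13 negative and heat shock genes one of -0.11. Of these lists, 6 no longer stood apart in 1 setting each: secondary and tertiary granule proteins (0.07) and heat shock genes (-0.08) without the filter on low values, eosinophil, basophil and mast cell genes (0.09) with mean FPKM of at least 5, and mature neutrophil genes (0.04), NADPH oxidase subunits (0.11) and B lineage genes (-0.05) with a pseudocount of 5. Cytoskeletal medians were -0.04 for formins and -0.09 for SRF and MRTF targets (percentile 3.72).

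In Het against WT Lin- cells, 142 genes were higher and 7 lower, and the higher genes were led by proteins of neutrophil granules. S100a8 stood at an FPKM of 21.1 in WT, 2935 in Het and 26.6 in KO, and S100a9 at 17.8, 2934 and 24.4. Ngp, with a log2 ratio of 7.38, Camp at 7.30 and Retnlg at 6.76 completed the first 5. Of 21 measured secondary and tertiary granule proteins, 20 passed, and the list median was 4.45 (percentile 100). Mature neutrophil genes had a median of 1.62 with 9 of 22 passing, among them Pglyrp1 at 4.67 and Fpr2 at 3.59. NADPH oxidase subunits had one of 1.11 with 4 of 7 passing, led by Cybb at 3.50. Eosinophil, basophil and mast cell genes had one of 1.13 with 8 of 16 passing, led by Ear6 at 5.01 and Ear2 at 4.90, which share fragments, and with Prg2 at 4.57. Monocyte genes were at 0.73, with Lgals3 at 3.02 and Fn1 at 2.13, inflammatory cytokines at 0.67, with Ccl6 at 3.34 and Il1b at 2.80, and primary granule proteins at 0.47, with Hp at 3.54 and Elane at 1.39. Csf3r and Cebpe, of the lineage regulators, were at 1.91 and 2.55.

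Most of these genes were abundant in the Gr1+Mac1+ libraries. Without the genes at least 4-fold higher in the WT Gr1+Mac1+ than the WT Lin- library, a setting chosen after seeing the data, 8 of the 142 were left. Other lists of this comparison were immediate-early genes at 0.45, megakaryocyte and platelet genes at 0.45 with Thbs1 at 1.37, stromal and endothelial genes at 0.59 with Col1a1 at 1.08, and T and NK cell genes at -0.27. SRF and MRTF cytoskeletal targets stood apart as higher at 0.13, with 18 of 18 positive and none passing, and replication-dependent histones as lower at -0.17, with 26 of 33 negative. Between the fractions, 16 of 19 SRF and MRTF targets and 18 of 20 immediate-early genes were higher in Gr1+Mac1+ cells. The rise of these 2 lists in Het Lin- cells can thus not be told apart from the rise of genes abundant in Gr1+Mac1+ cells. Small medians apart as higher were 0.06 for both mitosis and DNA replication genes, 0.02 for erythroid genes and 0.01 for ribosomal proteins. Dendritic cell and MHC class II genes were at 0.24, but at 0.11 with mean FPKM of at least 5 and 0.10 without the filter on low values, neither apart, and heat shock genes were at 0.09, but at -0.00206 with mean FPKM of at least 5. Moap1 was again lower, at -2.74, with Podxl at -2.66 and Acyp2 at -1.14. The Het FPKM of Moap1 was listed as 0.000152, against 5.68 in WT. A value that low is hardly a measured level, so this ratio is uncertain. Against the Het library, the KO Lin- library had 10 genes higher and 127 lower.

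In Het against WT Gr1+Mac1+ cells, 4 genes were higher and 11 lower. Cd14 had a log2 ratio of 2.02 (counting SE 0.08), Hspb1, a small heat shock protein, one of 1.15, and Col1a1 went from an FPKM of 4.42 to 9.87; Scarna10 was listed at 0 in WT and at 964 in Het. The lower genes were led by Rpl26 at -2.31, Hbb-b2 at -1.92 and Hbq1b at -1.23, all with copies, H2-Q7 at -1.21 and the metallothionein Mt2 at -1.16. All 31 erythroid genes had a negative log2 ratio, with a median of -0.51 (percentile 0) and 2 passing. Stromal and endothelial genes were at 0.38, megakaryocyte and platelet genes at 0.25, B lineage genes at 0.18, immediate-early genes at 0.17 and p53 target genes at 0.16, all apart as higher, as were SRF and MRTF targets at 0.10, lineage regulators at 0.08, heat shock genes at 0.08 and monocyte genes at 0.06. Type I interferon genes stood apart as lower, at -0.12 with 24 of 29 negative, where KO was at 0.11, as did T and NK cell genes at -0.11 and DNA replication genes at -0.08. With mean FPKM of at least 5, stromal (0.19), megakaryocyte (0.15), monocyte (0.06), T and NK cell (-0.07) and DNA replication genes (-0.08) no longer stood apart; without the filter on low values SRF and MRTF targets (0.04) and monocyte genes (0.06) did not. Secondary and tertiary granule proteins were at -0.04, not apart.

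**Figure D2:**
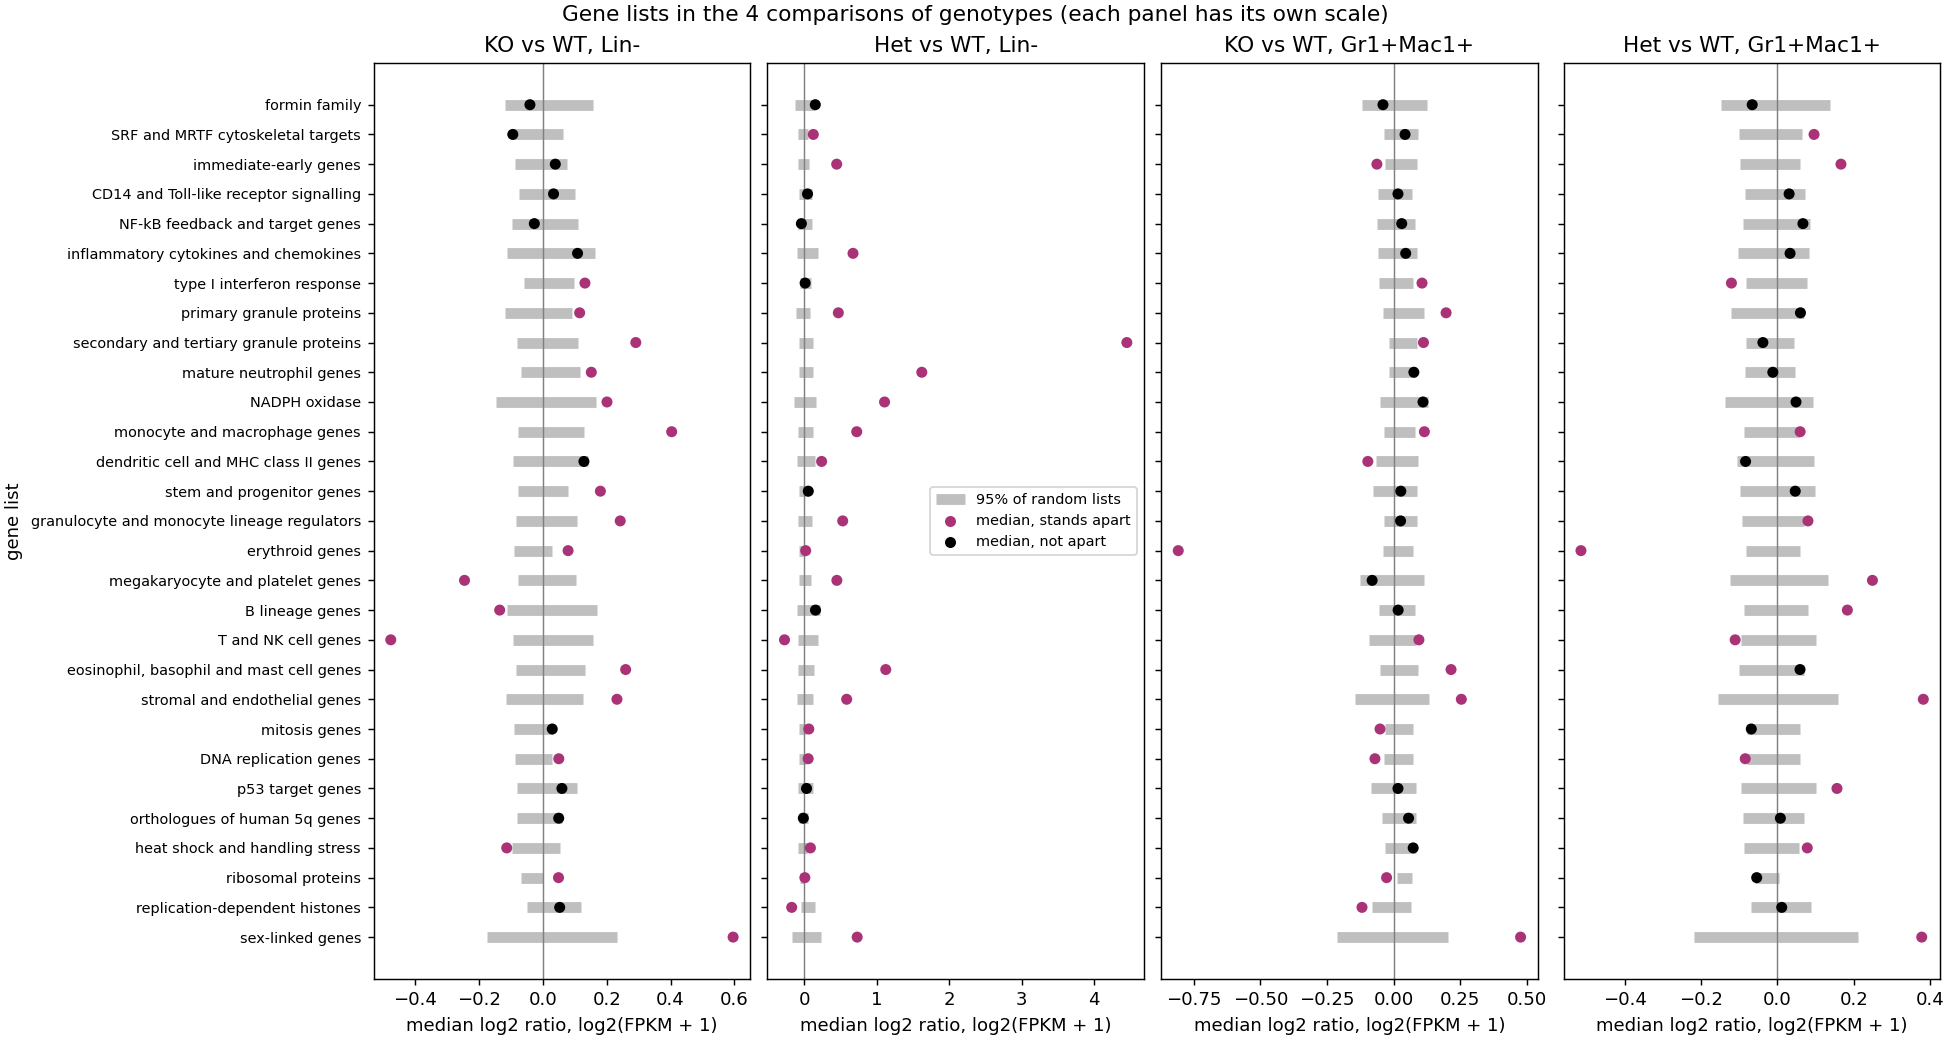
Median log2 ratio of the gene lists reported here (points) in the 4 comparisons of a genotype with WT, on the log2(FPKM + 1) scale, with grey bars for the central 95% of random lists matched on expression; each panel has its own axis range. Secondary and tertiary granule proteins reached 4.45 in Het Lin- cells, and erythroid genes -0.81 in KO and -0.51 in Het Gr1+Mac1+ cells.

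Sex-linked genes differed between the pools. Xist was at an FPKM of 54.2 in WT, 34.9 in Het and 38.7 in KO Lin- cells, and at 27.1, 18.02 and 19.9 in Gr1+Mac1+ cells. The Y-linked gene Eif2s3y was at 9.05, 17.6 and 17.96 in Lin- cells and at 10.9, 13.7 and 16.4 in Gr1+Mac1+ cells. Over the 5 genes and 4 comparisons, Xist was lower or a Y-linked gene higher than in WT in 20 of 20 cases. These cases are not independent. The fractions of a pool share mice, Het and KO share the WT libraries, and all of these genes would follow the mix of sexes. The labels give no sex, so the mix of sexes in the pools may differ with genotype, and any difference of Het or KO from WT, that of Cd14 included, may carry it.

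Het and KO were both compared with 1 WT library per fraction. In Lin- cells, H2-Q7, Lyz1, Rps27 and S100a6 were higher in both, beside 0.165 genes for independent lists, and Moap1 and Podxl lower in both, beside 0.00258. Unchanged libraries simulated with counting error against that WT library shared 0.987 calls over both directions. With the spread between KO and Het as the error they shared 0. That spread is a robust one over genes of similar level, so it does not cover genes noisier than those. In Gr1+Mac1+ cells Cd14 was higher in both, beside 0.00179, and Hbq1b lower in both, beside 0.00804. The simulation there gave 1.04 shared calls with counting error and 0.001 with that spread. A locus of Hba-a2 was also lower in both, but its symbol is held by more than 1 locus and so it is in neither of the lists behind these values. The log2 ratios of Het and KO correlated across genes, which are not independent replicates, with r = 0.48 and a covariance of 0.0272 in Lin- cells. The simulation gave r = 0.50 and a covariance of 0.0113 with counting error, and 0.0138 with the spread between KO and Het. In Gr1+Mac1+ cells r was 0.39 and the covariance 0.0204, beside 0.0103 and 0.0236. The WT library cannot be split, so part of any excess may come from it.

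KO effects in the 2 fractions shared no library. Across 10190 genes they correlated with Pearson r = 0.015 and a Spearman rank correlation of 0.036. Rps27 was higher in both fractions and Diap1 lower in both, beside 0.00383 and 0.00294 genes for independent lists, and no gene passed in opposite directions. For Het, over the same genes, the Pearson r was 0.038 and the Spearman rank correlation 0.0000196. Col1a1 and Hspb1 were higher in both fractions, beside 0.0534, and Col1a1 alone with mean FPKM of at least 5, beside 0.0240. No gene was lower in both, beside 0.00471, and H2-Q7 passed in opposite directions.

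Between the fractions, Lin- cells had the higher level of most erythroid, stromal, megakaryocyte and replication genes. Gr1+Mac1+ cells had that of most granule, neutrophil, monocyte and B lineage genes. These are levels of whole fractions, so they do not tell which cells of a fraction held a gene, those of the B lineage included. By limma with the pool as a block, 5931 of 11489 genes were higher in Lin- and 3491 higher in Gr1+Mac1+ cells. The median log2 ratio of all genes was 0.33 toward Lin-, and after rescaling by the median ratio the split was 4405 to 4574; list medians below are relative to the median of all genes. The p-values measure the spread over 3 pools that differ in genotype.

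The genes most raised in Lin- cells included the carbonic anhydrase Car1, with a mean FPKM of 1463 ± 51.9 (SD, n = 3) against 41.2 ± 12.0 (limma log2 ratio 5.15, SE 0.18, adjusted p = 0.000109), and the metallothionein Mt2 at 5.15. Atp1b2 followed at 5.10, Col1a1 at 4.64, Col1a2 at 4.63, Pklr at 4.55, Sphk1 at 4.47, Prss50 at 4.34, the osteoblast gene Bglap at 4.23 and Ces2g at 4.21. Of 31 erythroid genes 21 were higher in Lin- and 7 in Gr1+Mac1+ cells (median 1.31), and of 18 megakaryocyte genes 15 and 1 (1.51), with Pf4 at 3.24 and Vwf at 2.95. The abundant globin Hbb-b2, which has near-identical copies, went against the erythroid median. Its FPKM in WT was 268 in Lin- and 1919 in Gr1+Mac1+ cells, and in KO 729 and 2332. All 30 DNA replication genes were higher in Lin- cells (1.01; 27 after rescaling), as were 75 of 76 ribosomal proteins (0.74; 72 after rescaling). Stromal genes were split 8 to 2 of 12 (1.18), and stem and progenitor genes 12 to 5 of 23 (0.74), with Gfi1b at 3.79 and Ly6a at -3.02. Mitosis genes were split 19 to 3 of 28, and 9 to 7 after rescaling, with a median of 0.04; the 5q orthologues were split 15 to 5 of 25, and 11 to 9 after rescaling.

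The genes most raised in Gr1+Mac1+ cells were Camp (log2 ratio -9.01), S100a9 (-9.00), Ngp (-8.90), S100a8 (-8.75), Lcn2 (-8.54), Ltf (-8.42), Retnlg (-8.38), Chi3l3 (-8.00), Ear6 (-7.52) and Ear2 (-7.43). S100a9 had a mean FPKM of 57450 ± 4007 in Gr1+Mac1+ and 992 ± 1682 in Lin- cells (SD, n = 3; limma adjusted p = 0.00566), and the Lin- spread came from the Het library. All measured genes of 4 lists were higher in Gr1+Mac1+ cells: 27 secondary and tertiary granule proteins (median -6.70), 25 mature neutrophil genes (-4.76), 7 NADPH oxidase subunits (-4.45) and 27 monocyte genes (-3.60). B lineage genes were higher there in 22 of 24 (-3.15), with Vpreb3 at -4.91 and Cd79a at -4.32, primary granule proteins in 9 of 10 (-3.36), lineage regulators in 15 of 19 (-3.36), eosinophil, basophil and mast cell genes in 19 of 21 (-3.14), inflammatory cytokines in 18 of 19 (-3.03), with Il1b at -5.89, dendritic cell genes in 16 of 19 (-2.47) and T and NK cell genes in 16 of 24 (-1.36).

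Signalling and cytoskeletal lists were also higher in Gr1+Mac1+ cells. SRF and MRTF targets passed in 16 of 19 (-1.67), with Cnn2 at -3.66, and immediate-early genes in 18 of 20 (-2.71), with Klf2 at -3.90. Toll-like receptor signalling genes passed in 24 of 31 (-1.96), with Cd14 at -4.57 (SE 0.30), NF-kB genes in 21 of 24 (-1.87) and interferon genes in 24 of 29 (-1.48). Of 9 formins, 5 were higher in Gr1+Mac1+ and 2 in Lin- cells. Fmnl1 was at -2.87, Diap2 at -2.10 and Diap3 at 0.91, while Diap1 had a log2 ratio of -0.22 (limma adjusted p = 0.444). The Diap1 value averages over pools that lack 1 or both copies of it, so it does not show equal levels in the fractions. In WT its FPKM was 57.1 in Gr1+Mac1+ and 36.0 in Lin- cells, and in KO 4.07 and 6.07. Heat shock genes were split 10 to 12 of 24 (-0.57), p53 targets 9 to 11 of 23 (-0.65), histones 0 to 21 of 43 (-0.80), and sex-linked genes 3 to 0 of 5 (0.02). Adjusted over the list alone, the counts were equal for all lists but 2: NF-kB genes higher in Lin- became 3 in place of 2, and histones higher in Gr1+Mac1+ became 16 in place of 21.

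**Figure D3:**
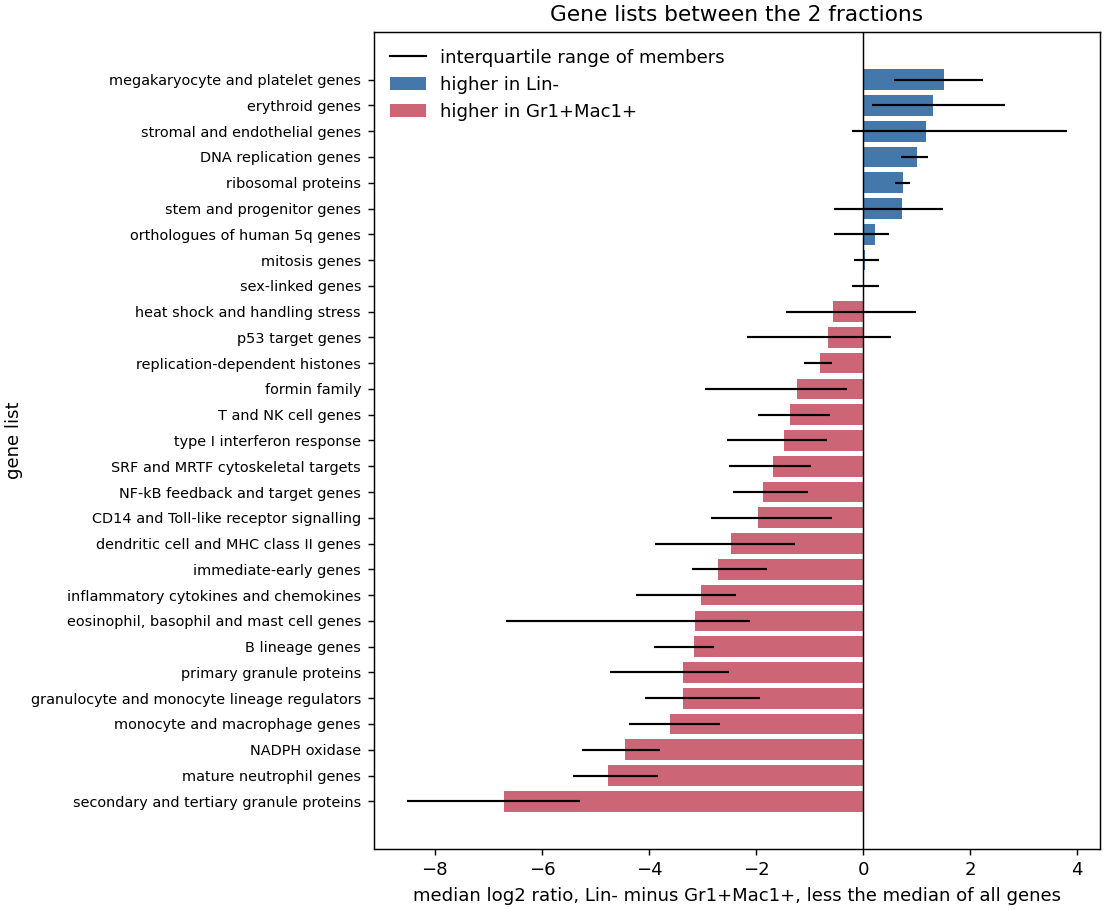
Median log2 ratio of Lin- minus Gr1+Mac1+ cells for the gene lists reported here, less the median of all genes, on the log2(FPKM + 1) scale over 3 pools (bars), with lines for the interquartile range of the members. Megakaryocyte genes stood at 1.51 and secondary and tertiary granule proteins at -6.70.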

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

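The erythroid tests of this part were chosen after the results were seen. The differences between fractions given here were not tested, since each fraction has 1 library per genotype.

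Erythroid genes differed between the fractions by -0.89 in KO (median log2 ratio against WT 0.08 in Lin- and -0.81 in Gr1+Mac1+ cells) and by -0.54 in Het (0.02 and -0.51). Lower erythroid expression in each cell of both fractions would also lower the list in KO Lin- cells, if the shares of cells there stayed equal. The lower quartile of the list there, -0.0304, lies above the bound of -0.26 and argues against that case. List levels are those of a whole fraction, so a larger share of erythroid cells in KO Lin- could hide a fall per cell. A smaller share of erythroid cells in the Gr1+Mac1+ fraction, which the beads should largely exclude, may account for the pattern. The genes were lower together in KO, with an upper quartile of -0.59 and 29 of 31 negative. Hbb-b2, which has near-identical copies, was higher, at an FPKM of 1919 in WT and 2332 in KO. The quartile restates the fall, so it cannot tell a smaller share from lower expression per cell in this fraction alone. Whether a share of erythroid cells differed through the sort or through the genotype stays open too, and the pools also differed in sex-linked genes.

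Of single genes, H2-Q7 in Het went opposite ways, with a log2 ratio of 1.75 in Lin- and -1.21 in Gr1+Mac1+ cells, a difference of -2.95. Both loci of Hba-a2 did so in Het, with differences of -2.94 (1.43 and -1.50) and -2.86 (1.41 and -1.45). All of these have near-identical copies. Of lists, T and NK cell genes in KO differed by 0.57 (-0.48 in Lin- and 0.10 in Gr1+Mac1+ cells). DNA replication genes differed by -0.12 in KO and by -0.14 in Het, and ribosomal proteins in KO by -0.07.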

How the results depend on the processing

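Settings that left out genes enriched in Gr1+Mac1+ cells, took off part of the Het Gr1+Mac1+ level or left out erythroid genes were chosen after seeing the data; the others were planned. Counts by the size rule depended strongly on its criteria, and the cause was not tested beyond what each criterion removes or admits. Counts are given as higher in KO Lin-, Het Lin-, KO Gr1+Mac1+ and Het Gr1+Mac1+ cells (15, 142, 5 and 4) and lower (4, 7, 11 and 11), where they moved by over 1.5 times. Without the interval criterion, 57 (KO Lin-), 44 (KO Gr1+Mac1+) and 40 (Het Gr1+Mac1+) genes were higher and 48, 46, 51 and 46 lower. With FPKM of at least 20, 7, 49, 2 and 2 were higher and 2, 3, 5 and 7 lower. With no filter on low values, 26 (KO Lin-), 245 (Het Lin-) and 14 (KO Gr1+Mac1+) were higher, and 20 and 20 lower in Gr1+Mac1+ cells. At 3-fold, 3, 86, 3 and 2 were higher, and 2 (KO) and 3 (Het) lower in Gr1+Mac1+ cells. A pseudocount of 5 gave 7, 86, 3 and 2 higher, and 3 and 5 lower in Gr1+Mac1+ cells; one of 0.1 gave 9 lower in KO Lin-, 21 lower in KO Gr1+Mac1+ and 7 higher in Het Gr1+Mac1+ cells. Of the 142 genes higher in Het Lin- cells, 8 were left without the enriched genes, and with 6% of the Het Gr1+Mac1+ level taken off 15 genes were higher.

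Rescaling by the median ratio moved none of these counts by over 1.5 times, no list call and no Diap1 level. Over 592 recomputed list medians, 560 kept their call, 21 lost it, 10 gained one and 1 reversed, heat shock genes in Het Lin- cells, from 0.09 to -0.00206 with mean FPKM of at least 5. Of 22 list medians above 0.26 in size over the 4 comparisons, 20 kept their call in all settings; the others were secondary and tertiary granule proteins in KO Lin- cells and stromal and endothelial genes in Het Gr1+Mac1+ cells. Of 144 recomputed log2 ratios of named genes, 106 stayed within counting error, 38 moved beyond it and none changed sign. With mean FPKM of at least 5, the correlation of Het and KO effects was 0.52 in Lin- and 0.37 in Gr1+Mac1+ cells, and that of KO effects in the 2 fractions 0.036; without the enriched genes the first was 0.51. Genes between fractions stayed within 1.5 times in all settings: leaving out a pool gave 5341 to 5690 higher in Lin- and 3144 to 3355 higher in Gr1+Mac1+ cells, and without the replicate block 6052 and 3530. Counting error limits single genes, and the lack of replicates limits every comparison of genotypes.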

Other observations

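The tests of Cd14 against other gene groups, a midpoint and the Diap1 level, and all tests of the granule genes, were chosen after the results were seen; those of the region around Diap1 and of other splits were written before.

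Cd14 was higher in Het and KO Gr1+Mac1+ cells. A larger share of monocytes is argued against by the other monocyte and macrophage genes, with a median log2 ratio of 0.12 in KO (upper quartile 0.41), and a general inflammatory rise by NF-kB and cytokine genes, with a median of 0.0367 (upper quartile 0.13), both bounded by 1. A shift of most genes around Diap1 is argued against by the 64 other genes within 5 Mb, whose median absolute log2 ratio in KO lay at percentile 44.8 of matched sets, though it lay at 98.5 in Het; a variant that acts on Cd14 alone stays open. An effect in cis on the targeted chromosome stays open, since the midpoint of WT and KO, 74.4, lies within the Het interval of 67.4 to 75.4. Any effect of equal size for each copy lost would give that midpoint, in cis or not, so the test cannot favour cis. An effect that follows the Diap1 level in a straight line stays open too: it predicts 66.8, just under that interval, but with the counting error of all values the Het level less this prediction was 4.64 (95% interval -1.81 to 11.1), and less the midpoint -2.94 (-8.14 to 2.21). The spread between mice is in neither interval.

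Granule genes were higher in the Het Lin- library. An effect that grows with the number of Diap1 copies lost is argued against by the KO Lin- library, where their median log2 ratio was 0.29, with an upper quartile of 0.40 under the Het lower quartile of 3.45. Of the 47 granulocyte-list genes at least 20-fold lower in WT and KO Lin- than in WT Gr1+Mac1+ cells, 100% had a Het Lin- excess above 1% of their Het Gr1+Mac1+ level, with a median of 5.44%. The count above 1% restates their rise. It cannot tell granulocytes carried over from the Gr1+Mac1+ fraction from granule genes expressed by Het Lin- cells themselves. The shares were alike, with quartiles of 4.83% and 6.13%. Expression by Het Lin- cells in proportions unlike those of the Gr1+Mac1+ library is thus argued against for these 47 genes. Het Lin- cells that expressed them in the same proportions stay possible. The excess was not limited to the granulocyte lists. All 498 genes of that kind, the 47 included, had a median of 5.27% (quartiles 3.99% and 6.63%) with 90.8% above 1%. For 10 monocyte genes the median was 5.02% and for 5 dendritic cell and MHC class II genes 6.27%. No list was freed of genes that granulocytes express as well, so these values cannot show an excess from other cell types. A share of the whole fraction stays open as well, since the 8 B lineage genes of that kind had a median excess of 2.89%, just within 2-fold of the 5.59% of secondary and tertiary granule proteins. That margin is narrow, as the same genes differed by -2.11% between the KO and WT Lin- libraries, and Mpo, abundant in all Lin- libraries, had an excess of 1.08%. All 13 measured B lineage genes had a median of 2.83% with a lower quartile of -0.86%, and 61.5% of them lay above 1%. Single genes were uneven, with Cd79a at 5.41%, Pax5 at -0.53% and Cd14, itself higher in KO than WT Lin- cells, at 0.87%.

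For the fractions, the 6 libraries allow 10 splits into 3 and 3, too few for a share under 0.05. Without the pool block the real split gave 9582 genes and was the only one, 1 of 10, to reach that number; the highest of the others gave 3.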
